A study of Mus musculus with 8 samples.

How the data were processed

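RNA of 8 cultures of Th2 cells (4 WT, 4 ARcKO, all with DHT) was made into libraries with the SMART-Seq HT and Nextera XT kits, per the labels' protocols. These kits do not keep the strand, so reads from a gene and from an overlapping antisense partner cannot be told apart. Reads were trimmed with Trimmomatic 0.33, aligned with HISAT2 2.1.0 to mm10 and counted per gene with featureCounts of Subread 1.6.5, per the submitters' processing notes. The annotation version, the counting options and any filter on low genes are not given in the sources used here.

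The table holds 18658 Ensembl genes in 8 columns. The deposited signal values are read counts scaled by the authors to CPM with a further factor per library; the scaling is not named in the labels or the header. Each value is a whole multiple of 1 step per library, the value of 1 read, which ran from 0.0584 to 0.0775. Divided by that step, 100% of the values came out whole within 0.001 reads. The implied factors per library ran from 0.974 to 1.02 and matched, to 3 digits, TMM factors recomputed with edgeR from the recovered reads. Every gene in the table had at least 1 read over the 8 libraries. A floor of 3 reads corresponds to 0.175 to 0.232 in the deposited unit. Floors cover counting error only, since reads without molecular identifiers are not independent molecules. The 10 most abundant genes took 5.90% to 6.25% of the reads.

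Symbols and coordinates were taken from GENCODE M21 (GRCm38, which is mm10) for 18552 of the gene IDs. The WT and ARcKO groups and replicate numbers came from the sample titles. The libraries were compared in pairs by a chi-square test of their recovered reads: within a group the statistic per degree of freedom ran from 3.81 to 20.0, so no library repeated another.

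The main comparison was limma 3.58.1 (R 4.3.3) with a mean-variance trend on log2(deposited value + 1), over the 9047 genes with a mean value of at least 10, with Benjamini-Hochberg adjustment and a threshold of 0.05. The design had been written for normalised values or raw counts; the values proved to be scaled counts, so limma stayed the main test and count tests on the recovered reads were alternatives. edgeR 4.0.16 called 1457 genes on the recovered reads (908 higher, 549 lower), of which 1424 were shared with limma. Low genes have understated changes on this scale. Single values were tested by exact two-sided permutation over 70 arrangements. The 6 genes named in advance had permutation p-values adjusted together, giving 0.0571 for Ar, Il5 and Gata3, 0.171 for Il13, 0.240 for Il4 and 0.257 for Dusp2. Ar, Il5 and Gata3 each had the smallest p that the 70 arrangements allow (0.0286). Their adjusted value above 0.05 is therefore no evidence against a change.

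Of 29 gene lists fixed before the data were examined, 24 had at least 4 tested members or were the type 2 cytokines, and were tested with camera at a preset correlation of 0.01. An estimated correlation and fry were alternatives. The genes named were the 10 largest changes in each direction with separated groups, 6 genes named in advance (Ar, Il4, Il5, Il13, Gata3 and Dusp2), and up to 4 members per list by p. Predicted gene models outside the top 3 of a direction were not named. Of the genes this rule takes, 26 list members that did not pass (log2 change -0.52 to 0.39) were counted in their lists and not named. Alternatives were other pseudocounts, filters, scalings, tests, library weights, each library left out and a replicate block. Added after the data were seen were a mean of at least 1, edgeR without the filter, library totals alone, reads thinned to 1 depth and a correction for GC content and length.

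The fits were tested on simulated counts for the ARcKO against WT comparison, drawn for the real genes with 200 changed. Each gene was drawn on its own, without trends shared between genes, and fewer genes changed than were called in the real comparison. The rates below may therefore not carry over to the real libraries. Over 9047 genes, limma recovered 50 of 50 genes at a log2 change of 1 and 50 of 50 at -1, with 40 of 50 at 0.5 and 39 of 50 at -0.5, and 13 of its 192 calls were false.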

Results

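Messenger RNA was sequenced from mouse Th2 cells, the CD4 helper T cells that make the cytokines of allergic inflammation, with and without the androgen receptor. Naive CD4 T cells from lymph nodes of C57BL/6 mice aged 8 weeks were polarised to Th2 cells in culture, and every culture received 10 nM dihydrotestosterone (DHT), the potent natural androgen, from day 4 for 48 h. WT cells came from mice with a floxed androgen receptor gene and no Cre, and ARcKO cells from mice that also carried CD4-Cre, which deletes the floxed part in T cells. Cre was thus present in ARcKO only, and any effect of its own cannot be told apart from loss of the receptor. Each group had 4 libraries. The recovered depth ranged from 12693338 to 16946131 reads in WT and from 15173041 to 17525701 in ARcKO. Values are given in the deposited unit, CPM after a further scaling factor per library, as mean ± SD with n = 4 per group. The labels do not say whether the 4 libraries of a group came from separate mice, so the p-values measure the spread between these libraries. All log2 changes are ARcKO minus WT on the log2(value + 1) scale.

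The targeted gene was read first. Ar (ENSMUSG00000046532, mm10 chromosome X, 98148769 to 98323215), which encodes the androgen receptor, stood at 71.3 ± 6.31 (SD, n = 4) in WT and 0.628 ± 0.216 (SD, n = 4) in ARcKO. The WT libraries held 896 to 1104 Ar reads and the ARcKO libraries 5 to 14. The log2 change was -5.48 (SE 0.13, limma adjusted p = 5.45e-10), and the exact two-sided permutation p was 0.0286, the smallest that 4 against 4 libraries allow. Every library therefore carried the Ar level of its label.

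**Figure D1:**
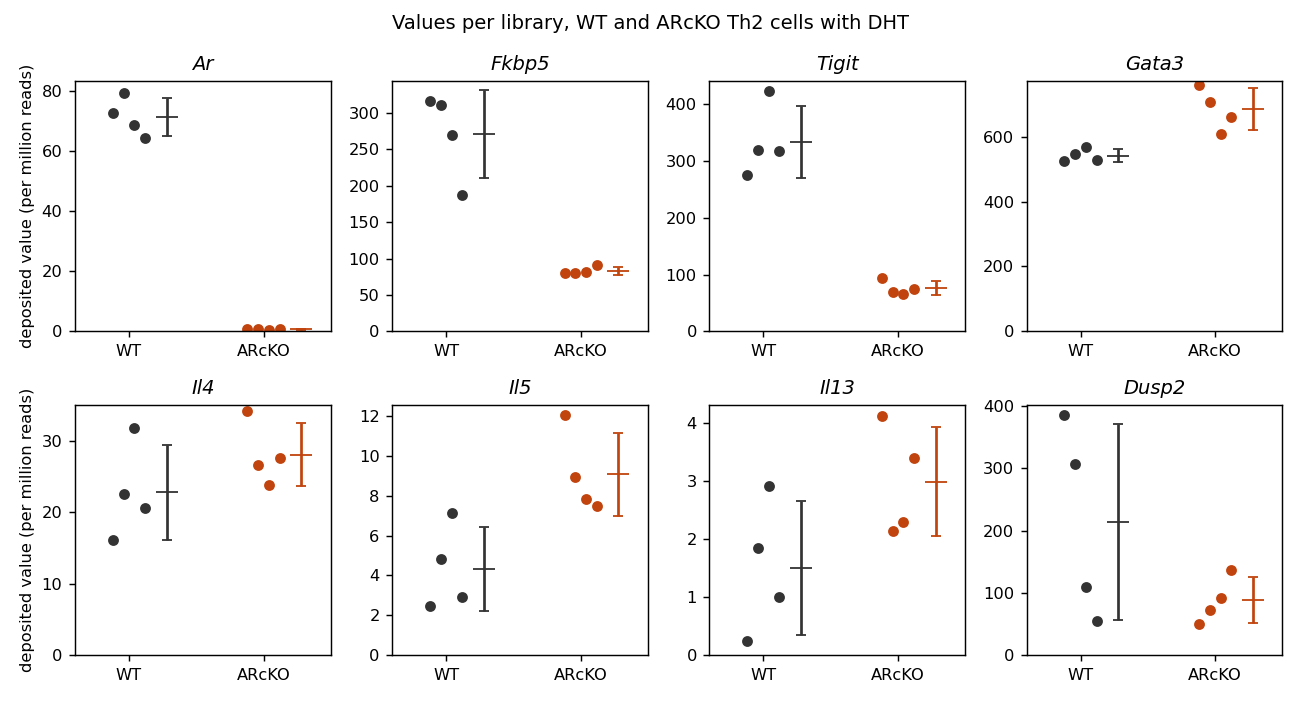
Deposited value (scaled CPM) of 8 genes in each library; dots are the 4 WT and 4 ARcKO libraries, and the dash with its bar is the mean ± SD. Ar was 64.4 or higher in every WT library and 0.820 or lower in every ARcKO library, while the groups overlapped for Il4, Il13 and Dusp2.

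Many genes differed between the groups by small amounts. Of 9047 genes with a mean value of at least 10, 909 were higher and 537 lower in ARcKO (limma, Benjamini-Hochberg adjusted p under 0.05), and the median absolute log2 change of these 1446 genes was 0.35. By at least 1 on the log2 scale, 20 genes rose and 21 fell. Among the changed genes, 1321 had all 4 libraries of one group above all 4 of the other. Over all tested genes 21.5% were separated in this way, against 2.86% by chance. The split of calls rested on the scaling: 62.9% of the calls were higher in ARcKO with the deposited scaling and 48.6% with library totals alone, where the median of all genes moved to -0.03. Leaving out WT 2, ARcKO 2 or ARcKO 4 brought the number of changed genes down to 884, 907 and 924, the higher genes numbered 593 without WT 2, and the lower genes 291 without WT 2, 315 without WT 4, and 294, 334 and 303 without ARcKO 2, 3 and 4.

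**Figure D2:**
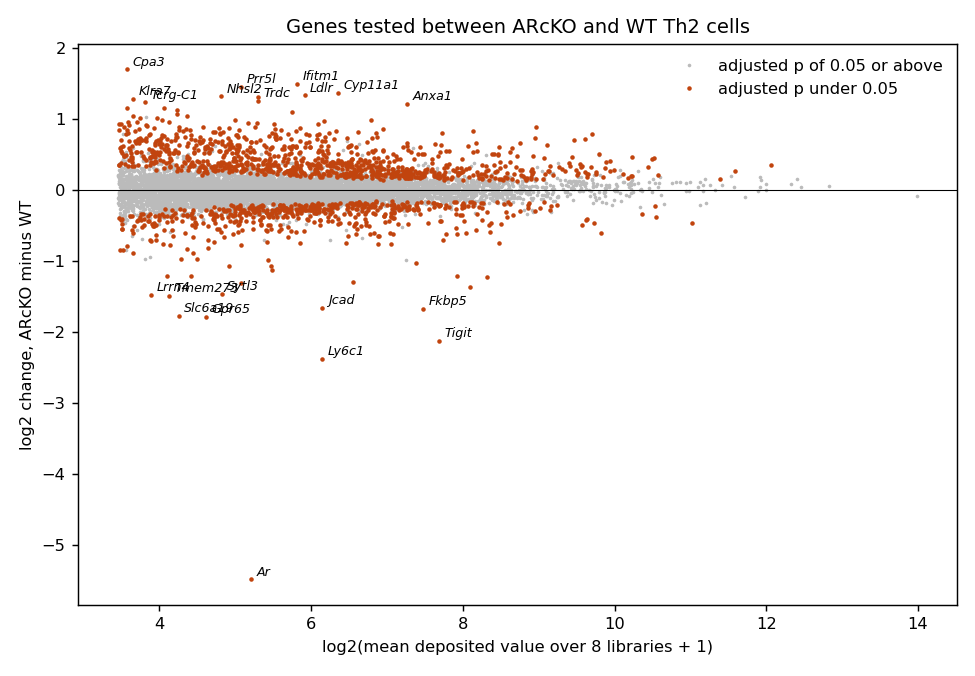
Log2 change of the 9047 tested genes against log2 of their mean value plus 1; orange points have a limma adjusted p under 0.05, grey points do not, and the 10 largest rises and 10 largest falls with separated groups are named, predicted gene models aside. Ar lies lowest at -5.48, Ly6c1 follows at -2.37, and Cpa3 lies highest at 1.70.

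After Ar, the largest falls were in Ly6c1, a surface marker of activated and memory T cells, from 118 ± 19.6 to 21.7 ± 1.20 (log2 -2.37), and in Tigit, an inhibitory receptor, from 334 ± 63.1 to 75.9 ± 12.8 (log2 -2.12). Fkbp5, a co-chaperone of steroid receptors and a known androgen target, fell from 271 ± 60.1 to 83.0 ± 5.32 (log2 -1.67, adjusted p = 3.27e-05). The acid-sensing receptor Gpr65 (log2 -1.78), the amino acid transporter Slc6a19 (-1.77), Jcad (-1.66), Tmem273 (-1.48), Lrrn4 (-1.47) and Sytl3 (-1.46) were the others named by size. The largest rise was in Cpa3, a protease known from mast cells, from 4.79 ± 1.82 to 17.1 ± 1.28 (log2 1.70, adjusted p = 0.000312). Cyp11a1, the enzyme that starts steroid synthesis from cholesterol, rose from 45.7 ± 16.4 to 116 ± 13.7 (log2 1.38), and Ldlr, which takes up cholesterol, from 33.3 ± 9.14 to 85.4 ± 21.5 (log2 1.34). The others named by size were Ifitm1 (1.496), Prr5l (1.46), Nhsl2 (1.33), the Ly49 family gene Klra7 (1.29), Trdc (1.26), Tcrg-C1 (1.24) and Anxa1 (1.22). Ly6c1 has a near-identical neighbour in Ly6c2 and Klra7 has close relatives, so reads of these genes may have been assigned to a relative and their values are uncertain.

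The series asks whether androgens restrain cytokine production by Th2 cells, so the type 2 cytokines were read next. Every library had DHT, so the comparison is of genotype and not of androgen treatment. It also reads mRNA and not secreted protein. Il4 (chromosome 11, 53602982 to 53618669) stood at 22.8 ± 6.64 in WT and 28.1 ± 4.37 in ARcKO, a log2 change of 0.32 that did not pass (limma adjusted p = 0.239; exact permutation p = 0.2). Il5 (chromosome 11, 53720794 to 53725106) and Il13 (chromosome 11, 53631324 to 53634702) lay under the filter on low values. Without the filter, Il5 rose from 4.33 ± 2.12 to 9.08 ± 2.09 (log2 0.98, adjusted p = 0.0254; exact permutation p = 0.0286), and Il13 stood at 1.496 ± 1.15 and 2.98 ± 0.941 (log2 0.77, adjusted p = 0.141; exact permutation p = 0.114). Il10 and Csf2, picked out after their values were seen, were also under the filter. Without it, Il10 fell from 15.3 ± 8.37 to 4.56 ± 1.48 (log2 -1.46, adjusted p = 0.00992) and Csf2 rose from 1.23 ± 0.258 to 2.52 ± 0.453 (log2 0.66, adjusted p = 0.0190). Single libraries decided several of these calls. Without WT 3, Il4 reached a log2 change of 0.49 (adjusted p = 0.0249) and Il13 one of 1.03 (adjusted p = 0.0230), and without WT 1 they stood at 0.17 (adjusted p = 0.483) and 0.47 (adjusted p = 0.306). Il5 did not pass without WT 1, WT 4, ARcKO 1 or ARcKO 2 (adjusted p up to 0.0824), nor Csf2 without WT 1, WT 2, WT 4, ARcKO 1 or ARcKO 2 (up to 0.0605). As a list, the type 2 cytokines did not pass camera, with 1 tested member in the filtered table (adjusted p = 0.631) and 7 without the filter (adjusted p = 0.450). The first restates Il4 alone. In the second, Il10 fell while Il5 and Csf2 rose, which a test of 1 direction averages out. Neither result shows that the cytokines were unchanged.

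Gata3 (chromosome 2, 9857078 to 9890034), the master transcription factor of Th2 cells, rose from 541 ± 19.3 to 685 ± 64.1 (log2 0.33, adjusted p = 0.00585; exact permutation p = 0.0286). Of 18 tested Th2 regulators and receptors, 4 rose, 1 fell and 13 did not pass. Adjusted over the list alone, 4 rose and 3 fell. Besides Gata3, the risers were the transcription factors Irf4 (log2 0.54) and Pparg (1.05) and the receptor Cd200r1 (0.70). Ccr8, named after its value was seen, fell by 0.42 on the log2 scale. Cd200r1 did not pass without ARcKO 2 (adjusted p = 0.0509), nor Ccr8 without WT 2, WT 4, ARcKO 2, ARcKO 3 or ARcKO 4 (up to 0.0914). Members of the list under the filter, named after their values were seen, fell without it: the transcription factor gene Bhlhe41 from 8.03 ± 1.24 to 3.84 ± 0.597 (log2 -0.90, adjusted p = 0.00279), and the IL-33 receptor gene Il1rl1 from 3.33 ± 2.76 to 0.749 ± 0.270 (log2 -1.14, adjusted p = 0.0345). Without WT 3 the Il1rl1 change was -0.76 (adjusted p = 0.0112), and it did not pass without WT 2, ARcKO 1, ARcKO 2, ARcKO 3 or ARcKO 4 (up to 0.0975).

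The study is known to have examined Dusp2, a nuclear phosphatase that inactivates MAP kinases, and the type 2 cytokines, so neither is independent evidence of a direction. Dusp2 (chromosome 2, 127336159 to 127338376) stood at 214 ± 158 in WT and 87.8 ± 37.0 in ARcKO, with overlapping groups. The log2 change of -0.99 (SE 0.53) did not pass (limma adjusted p = 0.231; exact permutation p = 0.257), and it became -1.505 (adjusted p = 0.0478) without WT 4 and -0.57 (adjusted p = 0.459) without WT 1. The spread within the groups went together with 80 other genes, Fkbp5 among them. As a set these had transcripts with GC-rich stretches, with a median highest GC content of any 200-nt window of 81.0%. Among 9 tested dual specificity phosphatases, 2 fell and none rose, with the same count adjusted over the list alone. These were Dusp1, from 29.9 ± 2.67 to 17.9 ± 0.549 (log2 -0.71, adjusted p = 0.000226), and Dusp10 (log2 -0.56). Of 17 tested MAP kinase cascade genes, Mapk3 (log2 0.40) and Mapk11 (0.27) rose and Mapk8 fell by 0.28, as they did adjusted over the list alone. Mapk11 did not pass without ARcKO 2 (adjusted p = 0.0509), nor Mapk8 without WT 2, WT 4, ARcKO 1, ARcKO 3 or ARcKO 4 (up to 0.0888).

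Cell cycle and cholesterol genes were higher in ARcKO. Of 24 cell cycle genes, 19 rose and none fell, and 21 rose adjusted over the list alone. The list had a median log2 change of 0.62. Mki67, the proliferation marker, rose from 153 ± 16.1 to 268 ± 14.1 (log2 0.81, adjusted p = 4.86e-05), and Cdk1, the mitotic kinase, from 39.2 ± 3.21 to 70.4 ± 3.10 (log2 0.83). Cdc20 (0.74) and Ccnb2 (0.70) rose likewise. Of 18 cholesterol synthesis and uptake genes, 14 rose and none fell, and 17 rose adjusted over the list alone. Beyond Ldlr, Insig1 (log2 0.82), Cyp51 (0.79) and Srebf2 (0.45), the master regulator of the pathway, were among them. Of 16 homing receptors, 7 rose and 1 fell, and 9 rose and 1 fell adjusted over the list alone. The chemokine receptors Ccr2, from 331 ± 39.5 to 527 ± 63.3 (log2 0.67), and Cxcr6 (0.64), the egress receptor S1pr1 (0.38) and the selectin ligand Selplg (0.33) rose, and Ccr8 fell.

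These were the 3 of 24 tested lists that passed camera with its preset correlation (adjusted p = 8.82e-18, 1.82e-09 and 0.00312). All 3 calls were lost with an estimated correlation, where adjusted p = 0.329 for the cell cycle, 0.785 for cholesterol and 0.214 for homing. They passed fry, which tests whether a list's genes move one way on balance (adjusted p = 0.00133, 0.0444 and 0.000311). The number of lists past camera was no larger than in other splits of the libraries, since 30 of 35 splits gave 3 or more. The camera adjusted p of the other lists ran from 0.0603 to 0.990. The mean log2 change and camera's direction differed in sign for the Th2 regulators (mean 0.06, camera down), and the median and camera's direction for the follicular helper list (median 0.01, camera down) and the myeloid markers (median -0.04, camera up). The counts of genes above come from the separate test of each gene.

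**Figure D3:**
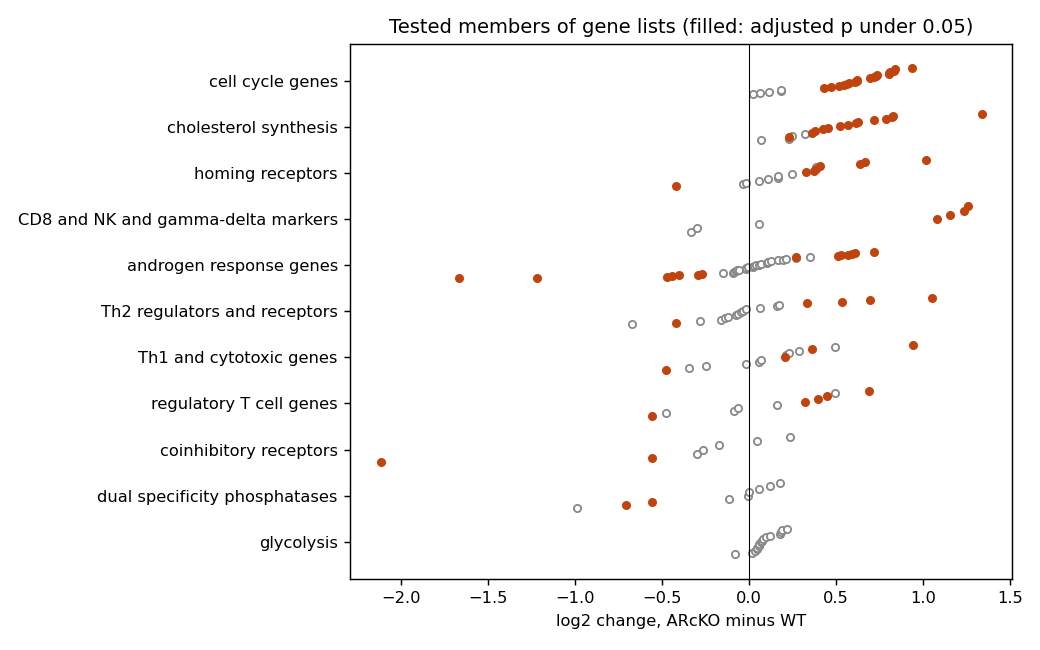
Log2 change, ARcKO minus WT, of each tested member of 11 gene lists; filled orange points have a limma adjusted p under 0.05 over all genes tested and open grey points do not. The cell cycle members lie to the right of 0, and the androgen response members lie on both sides.

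The changed members of the androgen response list split evenly. Of 37 tested members, 7 rose, 7 fell and 23 did not pass, and adjusted over the list alone 8 rose and 7 fell. Of all tested genes 16.0% changed, a smaller share than in this list. The cell cycle, cholesterol, homing and regulatory T cell lists had larger shares still, so the excess is not particular to the androgen response list. It was not tested. Tsc22d3, a glucocorticoid- and androgen-inducible regulator, fell from 446 ± 11.6 to 191 ± 6.77 (log2 -1.22, adjusted p = 5.61e-08), as did Fkbp5. The acyl-CoA binding protein gene Dbi rose from 25.5 ± 0.957 to 43.0 ± 6.38 (log2 0.72), and Uap1 rose by 0.57 on the log2 scale. Of the steroid receptors, Ar and Nr3c1 were tested. The glucocorticoid receptor Nr3c1 stood at 176 ± 12.3 and 150 ± 18.3 (adjusted p = 0.0709), and adjusted over the list alone both were lower. With the deleted gene Ar as the only other member, that adjustment leaves Nr3c1 at its unadjusted limma p of 0.0138. Nr3c1 passed without ARcKO 1 (adjusted p = 0.0206).

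Genes of other T cell states were read by list. Of 7 tested coinhibitory receptors, 5 did not pass, Tigit and Ctla4 fell, Ctla4 from 344 ± 64.4 to 231 ± 12.3 (log2 -0.56, adjusted p = 0.00442), and none rose; Pdcd1 stood at 39.9 ± 10.98 and 32.2 ± 3.19. The same count fell adjusted over the list alone, and the list passed camera without WT 1 (adjusted p = 0.00505) or WT 2 (0.0274), against 0.0739 with all libraries. With an estimated correlation and all libraries its adjusted p was 0.892. Of 13 Th1 and cytotoxic genes, Ccl5 (log2 0.95), Il12rb2 (0.36) and Tbx21 (0.21), the Th1 master factor, rose and Lta fell by 0.48. Adjusted over the list alone, 5 rose and 1 fell. Of 10 regulatory T cell genes, 4 rose, among them Ikzf2 (log2 0.69), Nrp1 (0.39) and Capg (0.32), and Ctla4 fell. Adjusted over the list alone, 4 rose and 2 fell. Of 12 naive and memory genes, Klf2 (log2 0.64), Id3 (0.56) and S1pr1 rose and none fell, against 4 and 3 adjusted over the list alone. Of 6 follicular helper genes, Bcl6 fell by 0.41 and none rose. Rora, the single Th17 gene tested, rose by 0.60 on the log2 scale. With single libraries left out, Il12rb2 (without any but WT 3, adjusted p up to 0.123), Bcl6 (without any but WT 1 and WT 3, up to 0.114), Capg (without WT 2, WT 4, ARcKO 2 or ARcKO 4, up to 0.0595), Rora (without WT 2, WT 4 or ARcKO 2, up to 0.0580) and Tbx21 (without ARcKO 3 or ARcKO 4, up to 0.0521) did not pass.

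Few members of the metabolic and stress lists passed. Of 16 glycolysis genes and 10 mitochondrially encoded genes none passed limma over all genes or over the list alone, with 0 at an unadjusted p under 0.05 and 0 by edgeR. Aldoa stood at 3638 ± 610 and 4089 ± 278, mt-Co1 at 3702.5 ± 382 and 4067 ± 257, and mt-Nd2 at 386 ± 37.2 and 418 ± 10.3. ARcKO 4 stood apart in mt-Atp6, at 299.9 against 66.2 to 77.3 in the other ARcKO libraries, and in mt-Co3, at 214.9 against 61.4 to 77.0. The log2 changes of 0.65 and 0.57 became 0.14 and 0.17 without it. Without WT 3, Aldoa passed (adjusted p = 0.0279), as did glycolysis (0.00109) and hypoxia (0.0341) in camera. Without WT 1, the log2 change of Aldoa was 0.09 (adjusted p = 0.542) and both lists turned down in camera (adjusted p = 0.848 each). With an estimated correlation and all libraries the adjusted p was 0.916 for both lists. Of 16 early response genes, Ier3 (log2 0.69) rose and the activation marker Cd69 fell from 62.4 ± 3.18 to 39.2 ± 3.93 (log2 -0.66). Of 13 hypoxia genes, P4ha2 (0.51) rose and Ddit4 fell by 0.65. Of 12 amino acid stress genes Psat1 (0.35) and Trib3 (0.34) rose, and 5 rose adjusted over the list alone. Of 12 endoplasmic reticulum stress genes Hsp90b1 (0.14) rose, and none did adjusted over the list alone. Of 12 interferon-stimulated genes Ifi27l2a rose, from 86.4 ± 4.63 to 159 ± 14.1 (log2 0.87), while Stat1 stood at 235 ± 80.5 and 179 ± 43.2. The early response, hypoxia, interferon and follicular helper counts were the same adjusted over the list alone. With single libraries left out, Hsp90b1 (without any but ARcKO 1, adjusted p up to 0.128), Trib3 (without WT 3, WT 4, ARcKO 2 or ARcKO 4, up to 0.0959), P4ha2 (without any but WT 3, ARcKO 3 and ARcKO 4, up to 0.0898), Psat1 (without WT 2, ARcKO 3 or ARcKO 4, up to 0.0648) and Ier3 (without WT 2 or ARcKO 2, up to 0.0600) did not pass.

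Markers of other cells were read as a check on the cultures. The constant-region genes of the gamma-delta T cell receptor rose together. Trdc went from 22.5 ± 4.55 to 54.6 ± 6.44 (log2 1.26, adjusted p = 0.000143), and Tcrg-C1 (1.24), Tcrg-C4 (1.16) and Tcrg-C2 (1.08) likewise. The CD8 and NK markers of the same list of 7, taken up after their values were seen, did not pass. Cd8a stood at 41.7 ± 6.46 and 34.7 ± 10.9, Cd8b1 at 129 ± 15.6 and 136 ± 28.3, and Klrd1 at 49.9 ± 6.30 and 39.5 ± 5.24. The list's camera adjusted p was 0.0603, it was 0.0335 without WT 3, 0.0181 without WT 4, 0.0201 without ARcKO 1 and 0.0282 without ARcKO 2, and adjusted over the list alone 4 rose and 1 fell. With an estimated correlation and all libraries its adjusted p was 0.892. Of 5 B cell markers, Ms4a1 fell by 0.55, and Cd19 stood at 21.1 ± 5.23 and 18.2 ± 3.31. Of 4 myeloid markers, Itgam rose from 7.51 ± 0.989 to 14.4 ± 1.53 (log2 0.85). Cpa3 was the single mast cell gene tested, the 1 tested stromal gene did not pass, and no erythroid gene reached the filter. Of 4 sex-linked genes, Uty fell by 0.20, and Ddx3y stood at 164 ± 22.1 and 134 ± 10.7 (adjusted p = 0.0542). Ms4a1 did not pass without any 1 library but WT 3 and ARcKO 1 (adjusted p up to 0.122), nor Uty without WT 2, WT 4, ARcKO 2, ARcKO 3 or ARcKO 4 (up to 0.112), while Ddx3y passed without WT 1 (0.0196) or ARcKO 1 (0.0384).

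Members of the lists that lay under the filter were also read without it, and those past 0.05 were named after their values were seen. They numbered 13, of which 7 rose and 6 fell, with Il5, Csf2, Il10, Bhlhe41 and Il1rl1 given above. The eotaxin receptor gene Ccr3, of the homing list, rose from 4.35 ± 0.504 to 13.5 ± 2.51 (log2 1.42, adjusted p = 8.70e-05), and the coinhibitory receptor gene Cd244a from 1.98 ± 1.29 to 5.50 ± 1.19 (log2 1.19, adjusted p = 0.00938). Gpr83, of the regulatory T cell list, fell from 15.8 ± 5.41 to 3.73 ± 0.624 (log2 -1.77, adjusted p = 0.000289). Fdps, of cholesterol synthesis, rose by 0.69 on the log2 scale (adjusted p = 0.0175). Of the androgen response list, Scd1 rose by 0.64 (adjusted p = 0.0453) and Zbtb16 fell by 0.82 (adjusted p = 0.0315). The myeloid marker Fcer1g rose by 0.55 (adjusted p = 0.0351) and the B cell marker Ebf1 fell by 0.57 (adjusted p = 0.0343). Single libraries left out ended several of these calls. Fdps did not pass without WT 2, WT 4, ARcKO 1 or ARcKO 3 (adjusted p up to 0.0607), Scd1 without any but WT 4 and ARcKO 3 (up to 0.138), and Zbtb16 without WT 1, WT 2, ARcKO 1 or ARcKO 4 (up to 0.0980). Fcer1g did not pass without any but WT 3 and ARcKO 1 (up to 0.101), nor Ebf1 without any but WT 3 and ARcKO 1 (up to 0.102).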

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

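The tests of a swap of libraries, of the gamma-delta genes and of the depth, GC and scaling of the cell cycle genes were chosen only after the results were seen. In 11 cases 1 of the 4 libraries of a group stood far from the other 3, with a gap above 0.829 of the group's range. Over 308 groups of values looked at, chance would give about 15.4 such cases. The cases are not independent, and WT 3 holds more of them than any other library, so this count does not speak for single libraries. WT 3 also stood apart on the second principal component, a summary of variation shared over the tested genes (21.6% of the variance). It lay at -15.8 there, against -5.83 to 12.1 in the other libraries. WT 4 had 16.9 M reads, against 12.7 to 13.4 M in the other WT libraries. Dbi was 24.1 in WT 2 and 26.0 to 26.1 in the others. Ldlr was 46.8 in WT 3, against 26.8 to 30.1 in the others, and Rora was 96.7 in WT 3, against 59.0 to 64.1 in the others. Cd244a was 3.91 in WT 3, against 1.24 to 1.46 in the others, and Il1rl1 was 7.43 in WT 3, against 1.52 to 2.44. In ARcKO 4, mt-Atp6 was 299.9, against 66.2 to 77.3 in the others, and mt-Co3 was 214.9, against 61.4 to 77.0. Dusp5 was 41.3 in WT 3, against 36.5 to 37.2 in the others, and 43.6 in ARcKO 2, against 40.5 to 40.7. Cd79a was 17.97 in ARcKO 2, against 14.8 to 15.2 in the others.

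Dusp2 spread from 55.0 to 386 within WT and from 49.7 to 137 within ARcKO. The values went in the order of the replicate numbers, falling from WT 1 to WT 4 (386, 307, 109 and 55.0) and rising from ARcKO 1 to ARcKO 4 (49.7, 72.7, 91.9 and 137). The labels do not say what these numbers order, so this decides nothing between the explanations. Within the groups, 80 genes with an SD above 0.2 followed the deviations of Dusp2 with r above 0.9. Of 576 rearrangements within the groups 1, the real one, gave as many. A swap of libraries between the groups is argued against by Ar, whose lowest WT value was 78.6 times its highest ARcKO value. A trend between libraries on GC-rich transcript stretches may account for the spread. The highest GC content of any 200-nt window had a median of 81.0% in the 80 genes and was 80.5% in Dusp2. That median lay above 100% of 10000 lists matched on expression and length (median 67.5%). The matched lists were not held to an SD above 0.2, as the 80 genes were. The excess may therefore belong to variable genes in general. A score of genes with such windows outside the 80 gave r = 0.75 (permutation p = 0.104; rho = 0.64, permutation p = 0.158; r = 0.18 without the 2 farthest libraries) but decides nothing, since the closest followers of Dusp2 are left out of it by construction, and the activation state stays open, since the early response list gave r = 0.65 (permutation p = 0.170; rho = 0.45, permutation p = 0.366; r = 0.39 without the 2 farthest; both r have an adjusted p of 0.170).

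Trdc and 3 Tcrg constant genes rose by 1.08 to 1.26 on the log2 scale. All 4 genes passed after thinning to 1 depth. Thinning keeps the expected ratios between libraries, so this decides nothing on the deeper ARcKO libraries. For other lymphocytes filling in for CD4 T cells, Cd8a, Cd8b1 and Klrd1 were read, with a mean log2 change of -0.19 (95% interval -0.62 to 0.24). These genes thus did not rise with Trdc. This decides nothing on the explanation, since their values had been seen before the test was set. A larger share of gamma-delta T cells, which the choice of naive CD4 T cells for culture would remove for the most part, cannot be told apart from a change within the cells: 5 other genes of that lineage, with 16 to 48 reads per library, had a summed log2 ratio of 0.34 (95% interval -0.39 to 1.08). Its parts went apart on few reads per group, from 26 in WT to 67 in ARcKO for Trdv5 and 13 to 25 for Trdv4, against 18 to 17 for Sox13, 22 to 24 for Cd163l1 and 23 to 15 for 5830411N06Rik, and the genotype also stays open.

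The cell cycle list had a median log2 change of 0.62. A trend on GC content or length is argued against by a median of 0.62 after its correction. The scaling factors per library ran only from 0.974 to 1.02, too close together for a change of this size. With library totals alone the median was 0.58. After thinning to 1 depth it was 0.60, but thinning keeps the expected ratios between libraries. It could hardly have lowered the median, so it decides nothing on depth. In each case 19 of the 24 genes passed. The genotype is left as a hypothesis among the explanations weighed, and what differs in the cells was not tested.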

How the results depend on the processing

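The alternatives marked as added were chosen after seeing the data, and the cause of a change was not tested unless stated. Ar kept its direction and call in every alternative that recomputed it. Changed genes numbered 832 (522 higher, 310 lower) with a mean of at least 50, which tests fewer genes, and 2271 (952 lower) with library weights; 1429 of these were among the 1446. With 1 library left out they ranged from 884 to 1807, higher from 593 to 1067 and lower from 291 to 740. With 1 library left out, the lower genes moved by over 1.5 times from 537 without WT 2 (291), WT 4 (315), ARcKO 2 (294), ARcKO 3 (334) or ARcKO 4 (303). TMM rescaling moved nothing, since the deposited values already carry those factors. Same-numbered libraries did not deviate together as a rule (correlations -0.31, 0.20, -0.12 and -0.23), so the values gave no clear sign of pairing. So few correlations cannot exclude it, and the labels leave it open. A replicate block gave 893 calls (604 higher, 289 lower), 866 of them shared. Lists past camera were 5 with edgeR, 5 with DESeq2, 5 with edgeR without the filter (added), 0 with an estimated correlation, and 3 to 6 with 1 library left out (6 without WT 3). Of 103 named genes 85 were called, and 60 of these kept their call and direction in every alternative that tested them. A mean of at least 50 left 38 of the 85 to test. Over all 2300 values of named genes 2117 were the same, 156 lost the call, 23 gained it and 4 turned direction, all in Cd8b1, which was not called (-0.0142 with the GC content and length correction, added, and -0.0335 to 0.170 with 1 library left out). Dusp2 also passed with library weights.

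Lists that did not pass turned direction in camera at these adjusted p-values. Without the filter: early response 0.911, interferon 0.839. With a mean of at least 50: follicular helper 0.872, androgen response 0.480, early response 0.912, myeloid 0.863. With edgeR: Th2 regulators 0.921, androgen response 0.658, early response 0.938. With DESeq2: Th2 regulators 0.913, androgen response 0.592, early response 0.994, interferon 0.913. With library weights: Th2 regulators, androgen response and early response, each 0.992. With the replicate block: Th2 regulators 0.931. With fry in place of camera: Th2 regulators 0.860, androgen response 0.721, interferon 0.984. With edgeR without the filter (added): regulatory T cell 0.759, androgen response 0.545, early response 0.759, interferon 0.545. With library totals alone (added): Th2 regulators and MAP kinase, each 0.955. With reads thinned to 1 depth (added): MAP kinase 0.999. With 1 library left out, adjusted p ranged from 0.491 to 0.985 for Th2 regulators, 0.667 to 0.985 for follicular helper, 0.510 to 0.977 for androgen response, 0.748 to 0.992 for MAP kinase, 0.740 to 0.985 for early response, 0.00109 to 0.848 for glycolysis, 0.0341 to 0.921 for hypoxia and 0.222 to 0.921 for interferon genes, with a turned direction in some. The type 2 cytokine list passed in none of the alternatives (without the filter 0.0659 to 0.956 with 1 library left out). With the main filter it held Il4 alone, and without the filter its members moved both ways. This is therefore no evidence that type 2 cytokines were unchanged.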

Other observations

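The tests of mitotic genes, of the corrected glucocorticoid list and of chromosomes, and the gene families with their members, were chosen only after results were seen. Of 9 gene families not among the fixed lists, 3 passed camera with an estimated correlation, all higher. With the preset correlation used for the fixed lists 7 passed, all higher, among them ribosomal proteins (adjusted p = 5.73e-06, 4 of 80 genes higher), complex I (0.000609, 2 of 36), the proteasome (0.0324, 5 of 34) and integrins (0.0376, 4 of 13). Of all tested genes 10.0% rose, so fewer single genes rose among the ribosomal proteins and complex I than overall. Of 7 tested tubulins 6 rose, among them Tubb4b from 182 ± 7.72 to 268 ± 12.4 (log2 0.55, limma adjusted p = 6.07e-05), and of 22 kinesins, the motors of the spindle and of transport, 13 rose and 1 fell; Kif11 is also in the cell cycle list. All 5 tested S100 calcium-binding protein genes rose, S100a10 from 538 ± 27.9 to 876 ± 27.4 (log2 0.70, adjusted p = 1.49e-05). With the estimated correlation, camera gave adjusted p = 0.0412 for the tubulins, 0.0258 for the S100 genes and 0.0258 for the kinesins, against 0.552 for ribosomal protein genes, 0.552 for the proteasome, 0.505 for complex I, 0.505 for CD3 chains, 0.648 for T cell receptor beta genes (2 of 18 higher) and 0.446 for integrins (4 of 13 higher, 1 lower). Ly6c2 rose by 0.54 (adjusted p = 0.0206; up to 0.0641 and not past without WT 2, ARcKO 3 or ARcKO 4) while its near-identical neighbour Ly6c1 fell by 2.37, and reads of the pair may not be assigned cleanly.

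Whether mitotic genes rose more than DNA replication genes was tested on members outside the fixed list. Of 34 genes of G2 and M phase 28 rose (mean log2 change 0.49), and of 23 S phase genes 10 rose (mean 0.30). The difference of the mean scores per library was 0.19 higher in ARcKO (exact two-sided permutation p = 0.0286, the smallest possible, with all 4 ARcKO libraries above all 4 WT). A shift of the cycling cells towards G2 and M may be one reading, found on the same data as the pattern.

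Tsc22d3 and Fkbp5 are also glucocorticoid targets, so a list of glucocorticoid-inducible genes was tested for a fall. Members already seen to fall, Tsc22d3 and Fkbp5 among them, were to be left out of it. The means below therefore understate any fall of the full group. A first run had by mistake kept Klf9 and Bcl6, whose falls were already known. Its 20 genes had a mean log2 change of -0.18 (95% interval over genes -0.34 to -0.02), with a camera p of 0.0611. Without the pair, 18 tested genes had a mean of -0.14 (95% interval -0.30 to 0.02), with 1 higher and 2 lower and a camera p of 0.241. The rule set before the first run counted an interval reaching 0 as evidence against a fall, which the corrected list would meet. That rule was replaced after the first run, because an interval from -0.30 to 0.02 still allows a fall, so the question is left open and neither run is a test planned in advance.

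The changed genes did not gather on a chromosome. Over 20 chromosomes 12.2% to 18.8% of the tested genes changed, and the smallest adjusted Fisher's exact p was 0.366.

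Of the 35 splits of the 8 libraries into 4 and 4, 1 gave as many changed genes as the real one, namely itself. It gave 1446 and the others at most 0 with limma. At an unadjusted p under 0.05 the others gave at most 1129, against 2792 in the real split. Each of the others mixes WT and ARcKO, so a difference between the groups widens their spread and lowers their counts. The comparison can therefore show no more than that the real split ranked first of 35. It does not cover a difference of mice or cultures that goes with the groups. For the number of lists past camera, chance cannot be excluded. The real split gave 3, 30 of the 35 splits gave as many, and the highest of the others gave 11. Scores of 5 of 24 lists, the cell cycle, cholesterol, homing, coinhibitory and gamma-delta lists, were fully separate between the groups, each with an exact permutation p of 0.0286 and an adjusted p of 0.137. As 0.0286 is the smallest p possible here, 5 separate lists among 24 could not have reached a lower adjusted p.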
